A study of Botrylloides leachii with 15 samples.

How the data were processed

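RNA sequencing was done on 15 libraries of the colonial ascidian Botrylloides leachii, with 3 libraries in each of 5 groups. The labels name 3 physiological states (active, mid torpor and fully torpid) and 2 tissues, ampullae and zooids. Ampullae and zooids were sampled from active and from mid torpor colonies. The torpid libraries are titled as colonies, and their source is given as ampulla cells; they were treated as torpid ampullae. The titles call the 3 libraries of a group biological replicates and do not say whether each came from a colony of its own, so p-values measure the spread between these libraries. Per the labels' protocols, RNA was isolated from fresh tissue with a column kit, and libraries were made from total RNA after removal of ribosomal RNA with Ribo-Zero Gold.

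Per the submitters' processing notes, Trimmomatic, HISAT2, RSEM and DESeq2 were used. Their versions, their order and the genome build are not given in the sources used here. The deposited tables hold estimated counts per gene model, not normalized, and FPKM values (fragments scaled to gene length and library size) that the authors computed. Counts were given for 13820 gene models and FPKM for 13326, of which 13318 had both. The highest value of any gene model over the 15 libraries was at least 1 for both units, so models below that level had been left out before deposit. Gene models carry identifiers such as Boleac.CG.SB_v3.S5.g10797; the files do not pair them with gene names, and no reference was used here. For this reason 46 gene lists written by gene symbol before the data were examined were not tested, and gene models are named by identifier only.

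Estimated counts were rounded to whole numbers. Gene models were kept by edgeR's filterByExpr by group, which left 10301 for testing and removed 3519. Library sizes were scaled by TMM, and CPM below means counts scaled to the TMM-adjusted library size by edgeR's cpm function. All 15 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 with robust dispersions, and each comparison was a contrast of group means in the two-sided quasi-likelihood F test. A gene model was called when its Benjamini-Hochberg adjusted p was under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. There were 7 contrasts: mid torpor minus active and torpid minus active ampullae, torpid minus mid torpor ampullae, mid torpor minus active zooids, zooids minus ampullae in active and in mid torpor colonies, and the interaction of tissue with state. The named identifiers were chosen by a rule fixed before the data were examined: the 2 largest increases and the 2 largest decreases among called models whose groups did not overlap and whose higher group averaged at least 10 CPM, without the overlap condition for the interaction.

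Library totals ran from 802226 to 3311031 counts in 14 libraries. The third replicate of mid torpor zooids held 17121 counts, so that 1 count there was worth 58.4 CPM before TMM scaling. Where all libraries of a group had 0 counts, the fold was given as a bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio was given with its exact 95% counting interval. These bounds and intervals cover counting error only. In simulated counts with the means and library sizes of the real data and 200 changed models, the edgeR test recovered 48% of models changed by a log2 fold change of 2 and 77% of those changed by 3 for torpid minus active ampullae. The shares were 51% and 83% for mid torpor minus active zooids, and 11% and 48% for the interaction.

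Because no gene names were used, tissue-biased gene models served as gene groups. They were chosen after the data had been seen. Models that differed between zooids and ampullae of active colonies were followed in torpid minus mid torpor ampullae. Models that differed between zooids and ampullae of mid torpor colonies were followed in torpid minus active ampullae. The groups contrasted for the choice and for the test thus had no library in common. The filter, scaling and dispersions came from the fit of all 15 libraries, so choice and calls were not fully independent. The 4 resulting sets were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on voom values, with an estimated correlation, and with fry; for the DESeq2 alternative camera was run on signed z values of the Wald test at the preset correlation alone. In simulated counts camera recovered a planted set of 300 models and called none of 100 unchanged sets at an unadjusted p under 0.05. The simulated models were drawn independently of each other, so this check cannot speak for sets whose models vary together. The estimated correlations were 0.206 and 0.118 for zooid-higher and ampulla-higher models of active colonies. For those of mid torpor colonies they were 0.202 and 0.127. The position of a library between active ampullae (0) and active zooids (1) was the difference of its mean log2 CPM over the zooid-higher and the ampulla-higher models, scaled to the means of those 2 groups; an active library took no part in choosing the models or the ends for its own position.

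Replicate numbers in the titles were checked for pairing by correlating deviations from group means over 6720 gene models. Active ampullae and active zooids of the same number deviated together (r = 0.215, 0.196 and 0.212), and all 6 libraries correlated best with their own number. No other combination of groups had every correlation above 0.1. These active pairs also share the set of the S number in their descriptions, so the number and the set cannot be told apart there. Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors or total counts in place of TMM, no filter, the DESeq2 test, fits of only the compared groups, blocks for the replicate number and for the set of the S number in the descriptions (each set holds 1 library of every group), limma on log2(FPKM + 1) or log2(FPKM + 0.1) for models with an FPKM of at least 1 in 3 libraries, a threshold of 1 on the log2 fold change, and each library left out in turn. Plots were drawn with matplotlib 3.10.9.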

Results

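Botrylloides leachii is a colonial ascidian whose filter-feeding individuals, the zooids, share a tunic and a network of blood vessels that ends in blind sacs, the ampullae, at the colony margin. In torpor, colonies of this species lose their zooids and persist as vasculature. The libraries compared active, mid torpor and fully torpid colonies, with ampullae and zooids sampled separately in the first 2 states. Each of the 5 groups had 3 libraries. Total counts ranged from 802226 (mid torpor ampullae, replicate 2) to 3311031 (active zooids, replicate 3), apart from the third mid torpor zooid library with 17121. By group and in order of replicate, they were 2717431, 2394193 and 1785964 in torpid ampullae, 2307547, 802226 and 1422526 in mid torpor ampullae, 2055843, 2950818 and 17121 in mid torpor zooids, 1622777, 1260721 and 2452218 in active ampullae, and 3251173, 2659892 and 3311031 in active zooids. Between 10779 and 12785 gene models had a count in the 14 deeper libraries, and 4479 had one in that shallow library.

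**Figure D1:**
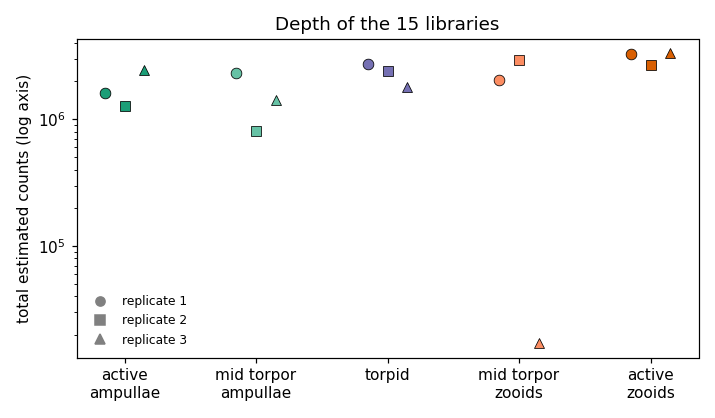
Total estimated counts (log axis) of the 15 libraries, 1 point per library, by group. Replicate 3 of mid torpor zooids stands at 17121 counts and all others at 802226 or more.

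Tissue was the main axis of the data among active colonies. Without the shallow library, the first principal component of the 500 most variable gene models carried 54.9% of the variance and placed the active zooids at 47.6 to 60.3, the active ampullae at -37.5 to -24.7 and the mid torpor ampullae at -39.8 to -34.3. The torpid libraries lay in between, at -10.04, -1.35 and 29.4, near the 2 deeper mid torpor zooid libraries at -0.345 and 21.1. The median Spearman correlation across gene models, which are not independent replicates, was 0.907 between active and mid torpor ampullae, 0.894 between torpid and mid torpor zooid libraries, and 0.736 between active ampullae and active zooids. Mid torpor ampulla libraries 1 and 2 were closer to each other than any other libraries of a group: their chi-square per degree of freedom was 2.19, against 9.31 to 52.3 for all other replicates, leaving out the shallow library, whose few counts keep this measure low. They were kept as 2 libraries, as the titles list them; the sources used here do not say whether they came from the same colony or RNA.

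To ask how the tissues differ in the active state, zooids were compared with ampullae of active colonies. Of 10301 gene models tested, 1359 were higher in zooids and 977 higher in ampullae, and the called models had a median absolute log2 fold change of 2.60. Boleac.CG.SB_v3.S39.g08859 stood at 121 ± 49 CPM (SD, n = 3) in active zooids and had no count in active ampullae, which made it at least 207-fold higher in zooids (edgeR adjusted p = 9.33e-05). Boleac.CG.SB_v3.S555.g11570, at 53.6 ± 37.8 CPM in zooids and without a count in ampullae, was at least 93.3-fold higher (edgeR adjusted p = 0.000477). The largest decreases belonged to abundant ampulla transcripts. Boleac.CG.SB_v3.S288.g06775 averaged 3110 ± 2680 CPM in active ampullae and 14.6 ± 9.74 in active zooids, a log2 fold change of -7.72 ± 1.35 (SE; edgeR adjusted p = 0.00139), and Boleac.CG.SB_v3.S227.g05334 averaged 961 ± 773 and 4.94 ± 4.24 CPM, a log2 fold change of -7.57 ± 0.95 (edgeR adjusted p = 0.000256). Both ampulla transcripts were much lower in active ampulla replicate 2, at 193.7 and 88.47 CPM. Active ampulla replicates 1 and 3 held 3676 and 5461 CPM of the former and 1236 and 1559 of the latter. The groups did not overlap at 2247 of the 2336 called models. Over all models the share was 38.7%, where chance gives 10%. Leaving out any of the 6 libraries left between 1588 and 2016 calls. Sizes moved more: without active ampulla replicate 3 the bounds were 113 and 50.9 and the log2 fold changes of the ampulla transcripts -6.95 and -6.94, without active zooid replicate 1 these were -8.33 and -8.41, and without active zooid replicate 3 the bound of Boleac.CG.SB_v3.S555.g11570 was 55. The median log2 fold change of all models was -0.05 with TMM, 0.06 with DESeq2 size factors and 0.09 with total counts, so single fold changes are relative to a median that scaling moves.

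In mid torpor colonies the same comparison of tissues called 759 gene models, 486 higher in zooids and 273 higher in ampullae. Boleac.CG.SB_v3.S370.g08559 stood at 29.8 ± 8.81 CPM (SD, n = 3) in mid torpor zooids with a single count over the mid torpor ampullae, a ratio of 109 with a 95% counting interval of 19.2 to 4330 (edgeR adjusted p = 0.00247). Boleac.CG.SB_v3.S183.g04055 was also higher in zooids, at 94.8 ± 92.6 against 2.31 ± 2.84 CPM, a log2 fold change of 5.96 ± 1.31 (SE; edgeR adjusted p = 0.0169). For both of these models 1 count of the shallow library entered the zooid mean as 35 CPM. Zooid libraries 1 and 2 held 34.84 and 19.65 CPM of the former and 201.5 and 47.92 of the latter. On the ampulla side, Boleac.CG.SB_v3.S527.g11201 averaged 117 ± 14 CPM in ampullae and 1.44 ± 1.69 in zooids, a log2 fold change of -5.80 ± 1.27 (edgeR adjusted p = 0.016). Boleac.CG.SB_v3.S24.g05687, at 10.4 ± 4.06 CPM in ampullae and without a count in zooids, was at least 17-fold lower in zooids (edgeR adjusted p = 0.0188). The lack of counts in the shallow library says little at this level, so its loss rests on zooid libraries 1 and 2. The share of calls higher in zooids was 64.0% with TMM and 74.8% with total counts as library size, which moved the median log2 fold change of all models from -0.05 to 0.12. The edgeR calls of 3 of these identifiers were lost with 1 library left out: Boleac.CG.SB_v3.S183.g04055 without ampulla replicates 1 and 3 or zooid replicate 1 (adjusted p = 0.0964, 0.0764 and 0.113), Boleac.CG.SB_v3.S527.g11201 without ampulla replicate 1 or zooid replicates 1 and 2 (adjusted p = 0.0599, 0.0831 and 0.0846), and Boleac.CG.SB_v3.S24.g05687 without ampulla replicates 1 and 2 or zooid replicates 1 and 2 (adjusted p = 0.0692, 0.0514, 0.0979 and 0.0729). The ratio of Boleac.CG.SB_v3.S370.g08559 was 54.8 (9.66 to 2180) without ampulla replicate 1 and at least 24.4 without replicate 3, which held its only count in ampullae. The bound of Boleac.CG.SB_v3.S24.g05687 was 9.83 and 7.23 without zooid replicates 1 and 2. The log2 fold change of Boleac.CG.SB_v3.S183.g04055 was 7.02 and 5.34 without ampulla replicates 2 and 3 and 4.67 without zooid replicate 1, and that of Boleac.CG.SB_v3.S527.g11201 was -6.76 and -5.10 without zooid replicates 1 and 2. The count fell to 185, 337 and 289 without mid torpor ampulla replicates 1, 2 and 3, to 216 and 487 without mid torpor zooid replicates 1 and 2, to 578 without the shallow library, and to 272 with ampulla libraries 1 and 2 summed into 1.

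The change within ampullae from the active state to mid torpor was small. It called 166 gene models, 55 higher and 111 lower in mid torpor, and the groups did not overlap at any of the 166; over all models the share was 23.0%, where chance gives 10%. The 2 largest decreases were near-complete losses. Boleac.CG.SB_v3.S90.g15205 averaged 214 ± 176 CPM (SD, n = 3) in active ampullae, with 1177 counts, and had 2 counts over the 3 mid torpor ampulla libraries, 491-fold lower with a counting interval of 136 to 4060 (edgeR adjusted p = 0.0169). Boleac.CG.SB_v3.S141.g02695 averaged 153 ± 114 CPM in active ampullae and likewise had 2 counts in mid torpor, 354-fold lower with an interval of 97.7 to 2930 (edgeR adjusted p = 0.00398). Both were much lower in active ampulla replicate 2, at 11.96 and 20.72 CPM. Active replicates 1 and 3 held 336.3 and 293.7 CPM of the former and 211.7 and 225.1 of the latter. In the other direction, Boleac.CG.SB_v3.S5.g10797 stood at 32.2 ± 16.6 CPM in mid torpor with 3 counts over the active libraries, 59.5-fold higher with an interval of 20 to 292 (edgeR adjusted p = 0.00546). Boleac.CG.SB_v3.S274.g06496 stood at 39.7 ± 18.3 against 0.667 ± 0.66 CPM, a log2 fold change of 5.58 ± 0.69 (SE; edgeR adjusted p = 0.00178). The count was 34, 35 and 83 without mid torpor replicates 1, 2 and 3, 66 without active replicate 3, and 44 with mid torpor libraries 1 and 2 summed into 1. With the DESeq2 test it was 311. Without mid torpor replicate 3 the balance was 43 higher and 40 lower. Sizes also rested on single libraries: Boleac.CG.SB_v3.S5.g10797 was 35.8-fold higher (11.5 to 180) without mid torpor replicate 1 and at least 32.4-fold without active replicate 3, Boleac.CG.SB_v3.S141.g02695 at least 119-fold lower without mid torpor replicate 1, Boleac.CG.SB_v3.S90.g15205 810-fold lower (145 to 32000) without mid torpor replicate 2, and Boleac.CG.SB_v3.S274.g06496 had a log2 fold change of 6.57 without active replicate 3. The edgeR call of Boleac.CG.SB_v3.S90.g15205 was lost without mid torpor replicates 1, 2 and 3 (adjusted p = 0.127, 0.081 and 0.0773), and Boleac.CG.SB_v3.S5.g10797 was not called by limma on log2(FPKM + 1) (adjusted p = 0.0845).

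Torpid ampullae differed from active ampullae at 1040 gene models, 471 higher and 569 lower, a balance that was 382 to 343 without torpid replicate 3. Gene models that were higher in zooids than in ampullae of mid torpor colonies were raised in the torpid libraries: 161 of 486 were called higher and 2 lower (270 and 5 when adjusted over the list alone), with a median log2 fold change of 1.59 against 0.04 for all models. Ampulla-higher models of mid torpor colonies moved the other way, with 159 of 273 called lower and 2 higher (205 and 3 when adjusted over the list alone) and a median of -1.53. Camera called both sets (adjusted p = 2.15e-25 and 9.4e-54 at the preset correlation), with an adjusted p = 0.0381 and 0.00194 with an estimated correlation; fry gave adjusted p = 0.00277 and 4e-06. Without torpid replicate 3 the medians were 1.04 and -1.36. With an estimated correlation the call of the zooid-higher set was lost without torpid replicate 3 (camera adjusted p = 0.0581), active ampulla replicate 1 (0.0735) or replicate 2 (0.0719), and also with DESeq2 size factors (0.0579) and with total counts (0.0767), and over all alternatives its adjusted p ran from 0.00647 to 0.0767; that of the ampulla-higher set stayed at 0.0076 or lower.

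Single gene models changed between torpid and active ampullae by larger factors. Both transcripts that were nearly lost in mid torpor had no count in torpid ampullae, which put Boleac.CG.SB_v3.S90.g15205 at least 489-fold lower (edgeR adjusted p = 0.00325) and Boleac.CG.SB_v3.S141.g02695 at least 353-fold lower (edgeR adjusted p = 0.000671). Boleac.CG.SB_v3.S101.g00429 rose from 2.07 ± 1.77 CPM (SD, n = 3) in active to 121 ± 44.1 in torpid ampullae, a log2 fold change of 5.86 ± 1.51 (SE; edgeR adjusted p = 0.0273); active zooid libraries 1, 2 and 3 held 942.5, 8.17 and 102 CPM of the same model. Boleac.CG.SB_v3.S370.g08558 stood at 14.2 ± 5.95 CPM in torpid and had 1 count over the active ampullae, 69-fold higher with an interval of 12.1 to 2760 (edgeR adjusted p = 0.00282); it averaged 26.6 ± 9.64 CPM in active zooids. The count of calls was 552 without torpid replicate 2, 552 without active replicate 2, 642 without active replicate 3, 725 without torpid replicate 3, and 242 when only the 6 libraries compared were fitted. The edgeR call of Boleac.CG.SB_v3.S101.g00429 was lost without torpid replicate 2 or active replicates 2 and 3 (adjusted p = 0.0598, 0.0968 and 0.0906), and its log2 fold change was 6.66 without active replicate 1. Boleac.CG.SB_v3.S370.g08558 was at least 16.2-fold higher without active replicate 1, which held its only count there, and 37.6-fold higher (6.57 to 1500) without active replicate 3. Without torpid replicates 1 and 2 the bounds were 311 and 325 for Boleac.CG.SB_v3.S90.g15205, and that of Boleac.CG.SB_v3.S141.g02695 was 224 without the first and 1.51 times below its full value without the second.

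**Figure D2:**
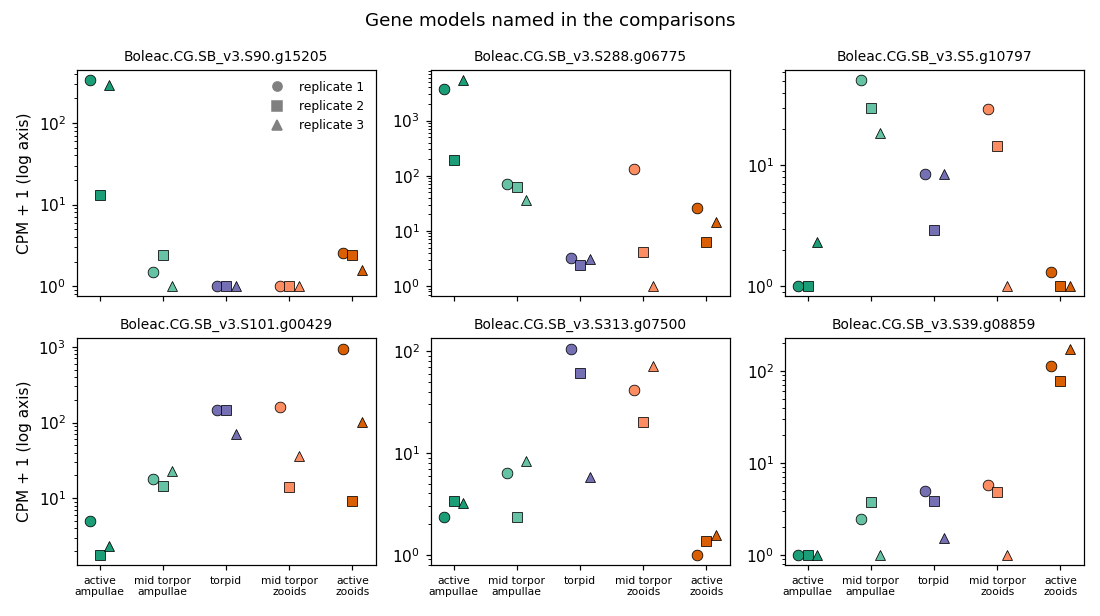
CPM + 1 (log axis) of 6 named gene models in each of the 15 libraries, 1 point per library, by group. Boleac.CG.SB_v3.S90.g15205 had no count in the torpid libraries, while Boleac.CG.SB_v3.S101.g00429 averaged 2.07 CPM in active and 121 in torpid ampullae.

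The step from mid torpor to torpid ampullae called 1160 gene models, 655 higher and 505 lower. This balance turned without mid torpor replicates 1, 2 and 3, to 145 higher and 243 lower, 264 and 309, and 200 and 269. Zooid-higher models of active colonies, chosen by a contrast of libraries outside this comparison, were raised: 425 of 1359 were called higher and 2 lower (635 and 8 when adjusted over the list alone), with a median log2 fold change of 1.84 against 0.10 for all models. With the 43 models that had no count in a whole group held at their bound, the median was 1.81. Ampulla-higher models of active colonies were lowered, with 269 of 977 called lower and 14 higher (373 and 31 when adjusted over the list alone) and a median of -0.83. Camera called both sets (adjusted p = 2.72e-23 and 2.52e-28), with an adjusted p = 0.0457 and 0.0136 with an estimated correlation; fry gave adjusted p = 0.0124 and 0.000438. Without torpid replicate 3 the zooid-higher median was 1.23. With an estimated correlation the zooid-higher call held without torpid replicate 1 (camera adjusted p = 0.0267), torpid replicate 2 (0.0492) or active zooid replicate 1 (0.0373). It was lost without torpid replicate 3 (0.0581), mid torpor ampulla replicates 1, 2 and 3 (0.0777, 0.0597 and 0.0673), active ampulla replicates 1, 2 and 3 (0.0529, 0.0781 and 0.0564) or active zooid replicates 2 and 3 (0.0593 and 0.0634). It was also lost with DESeq2 size factors (0.0768), with total counts (0.0831) and with the S-number set as a block (0.072), and over all alternatives its adjusted p ran from 0.0228 to 0.0831. The fry call of this set was lost without mid torpor ampulla replicate 1 (adjusted p = 0.0679).

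Among single models of this step, Boleac.CG.SB_v3.S222.g05240 and Boleac.CG.SB_v3.S540.g11383 had no count in mid torpor ampullae and stood at 37.6 ± 58 and 27.1 ± 26.7 CPM (SD, n = 3) in torpid ampullae, at least 47.5-fold and 35.2-fold higher (edgeR adjusted p = 0.0223 and 0.0155). Torpid replicate 3 held 195 of the 213 counts of the former and 106 of the 158 of the latter; without it the bounds were 5.73 and 16.6, and without mid torpor replicate 1 they were 23.9 and 17.7. Boleac.CG.SB_v3.S212.g04980 and Boleac.CG.SB_v3.S408.g09284 had identical values in every library, 12.5 ± 7.54 CPM in mid torpor ampullae and a rounded count of 0 in torpid ampullae, at least 27.9-fold lower (edgeR adjusted p = 0.000896), and 17.7-fold and 18.5-fold without torpid replicates 1 and 2. Identical rows can arise when reads are divided between near-identical copies, so these values are uncertain for either model. The count of calls was 721 and 621 without torpid replicates 2 and 3, 388, 573 and 469 without mid torpor replicates 1, 2 and 3, and 567 with mid torpor libraries 1 and 2 summed into 1. The edgeR call of Boleac.CG.SB_v3.S222.g05240 was lost without mid torpor replicates 1, 2 and 3 (adjusted p = 0.0932, 0.0571 and 0.0718), and that of Boleac.CG.SB_v3.S540.g11383 without mid torpor replicates 1 and 3 (adjusted p = 0.0721 and 0.0545). Limma on log2(FPKM + 1) called neither (adjusted p = 0.074 and 0.0614).

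Positions of single libraries between active ampullae and active zooids showed the same order. For torpid and mid torpor ampullae they use the same models and libraries as the set test of that step, so they are not a separate test. The torpid libraries were at 0.31, 0.47 and 0.74, mid torpor ampullae at 0.04, 0.06 and 0.00, and mid torpor zooids at 0.62, 0.51 and 0.52. Active ampullae, each placed without its own values, were at 0.07 to 0.17 and active zooids at 0.88 to 1.03. The torpid mean of 0.51 ± 0.22 (SD, n = 3) exceeded that of active ampullae by 0.40 and that of mid torpor ampullae by 0.47 (two-sided exact permutation p = 0.1 in each case, the smallest p that 3 against 3 libraries allow). The difference between torpid and mid torpor zooid libraries was -0.04 (exact permutation p = 0.8). In the shallow library the zooid-higher models gave -0.26 and the ampulla-higher models 1.59, so that its 0.52 is the difference of distorted values.

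**Figure D3:**
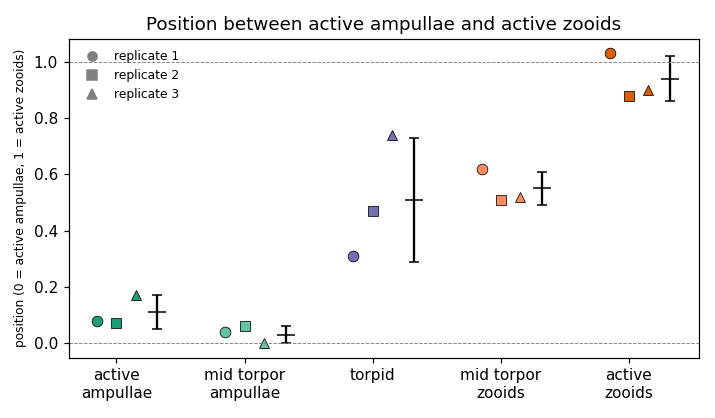
Position of each library on the scale from active ampullae (0) to active zooids (1), from tissue-biased gene models; points are libraries, bars are mean ± SD of 3. Torpid libraries spread from 0.31 to 0.74, above all active and mid torpor ampulla libraries, which lie at 0.17 or lower.

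Within zooids, mid torpor differed from the active state at 694 gene models, 373 higher and 321 lower. Boleac.CG.SB_v3.S313.g07500 rose to 43.3 ± 25.5 CPM (SD, n = 3) in mid torpor from 3 counts over the active zooids, 91.1-fold with a counting interval of 30.5 to 447 (edgeR adjusted p = 0.0083). Mid torpor zooid libraries 1, 2 and 3 held 40.49, 19.31 and 70 CPM of it, the last from 2 counts of the shallow library. Torpid libraries 1, 2 and 3 held 104.7, 59.7 and 4.83 CPM. Boleac.CG.SB_v3.S643.g12719 averaged 28.7 ± 15.4 CPM in active zooids and had no count in mid torpor zooids, at least 50.3-fold lower (edgeR adjusted p = 0.0156). Boleac.CG.SB_v3.S238.g05648, at 10.2 ± 4.49 CPM in active zooids, also had no count in mid torpor zooids and was at least 17.6-fold lower (edgeR adjusted p = 0.0131). In the shallow library 1 count equals 35 CPM, so its lack of counts says little at these levels. Both losses rest on mid torpor zooid libraries 1 and 2. Boleac.CG.SB_v3.S624.g12516 rested on 14 counts in mid torpor zooids and none in active zooids, at least 8.85-fold higher (edgeR adjusted p = 0.0228), and 1 count of the shallow library gave most of its mean of 13.6 ± 18.6 CPM. Tissue-biased models were also shifted. Against each active zooid library in turn, held out from the choice of models, zooid-higher models had median log2 differences of -1.85, -1.19 and -0.89 in the 2 deeper mid torpor zooid libraries, and ampulla-higher models 0.73, 0.76 and 0.67. In the corresponding comparison of mid torpor with active ampullae, the zooid-higher medians were -0.16, -0.07 and -0.91 and the ampulla-higher medians 0.02, -0.11 and -0.06; none of these medians was tested. Without mid torpor replicates 1 and 2 the edgeR calls of Boleac.CG.SB_v3.S643.g12719 (adjusted p = 0.0641 and 0.0922) and Boleac.CG.SB_v3.S238.g05648 (adjusted p = 0.0605 and 0.0875) were lost, and that of Boleac.CG.SB_v3.S624.g12516 without mid torpor replicate 1 or active replicates 1 and 3 (adjusted p = 0.102, 0.0636 and 0.0692).

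Normalization changed the direction of the balance in this comparison of zooids. With TMM 53.8% of the calls were higher in mid torpor, against 41.8% with DESeq2 size factors, and the median log2 fold change of all models moved from -0.13 to -0.27. The balance also turned without active replicate 2, to 258 higher and 317 lower. Sizes of the named changes moved with single libraries: Boleac.CG.SB_v3.S313.g07500 was 60-fold higher (20.1 to 294) without active replicate 1 and 174-fold (30.6 to 6900) without active replicate 3. Without mid torpor replicates 1 and 2 the bounds were 29.1 and 21.4 for Boleac.CG.SB_v3.S643.g12719, 10.2 and 7.49 for Boleac.CG.SB_v3.S238.g05648, and 4.36 and 16.3 for Boleac.CG.SB_v3.S624.g12516, whose bound was 5.83 and 5.62 without active replicates 1 and 3. The count was 241 and 161 without mid torpor replicates 1 and 2, 236 and 147 without active replicates 1 and 3, and 628 (453 higher) without the shallow library.

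The mid torpor responses of the 2 tissues were compared through the interaction, which called 37 gene models. Of these, 25 were lower in mid torpor than in active zooids and higher in mid torpor than in active ampullae by the signs of their fold changes, and 7 had the opposite signs. Within single tissues, 28 of the 37 were called in zooids and 12 in ampullae, so most signs in ampullae were not backed by a call. A called interaction by itself favours opposite signs. Boleac.CG.SB_v3.S555.g11570, at 53.6 ± 37.8 CPM (SD, n = 3) in active and 4.37 ± 5.36 in mid torpor zooids but without a count in active and at 7.59 ± 4.12 CPM in mid torpor ampullae, had an interaction log2 fold change of -9.93 ± 1.69 (SE; edgeR adjusted p = 0.0354). Boleac.CG.SB_v3.S30.g07155 averaged 257 ± 34.9 CPM in active and 48.1 ± 14.3 in mid torpor ampullae, against 10.7 ± 2.27 and 39.7 ± 27.1 in zooids, an interaction of 3.71 ± 0.68 (edgeR adjusted p = 0.0354). The latter mean rested on 2 counts in the shallow library, equal to 70 CPM, while mid torpor zooid libraries 1 and 2 stood at 31.1 and 17.9. The edgeR call of Boleac.CG.SB_v3.S555.g11570 was lost without any of 9 single libraries (adjusted p = 0.0503 to 0.0988) and that of Boleac.CG.SB_v3.S30.g07155 without any of 10 (adjusted p = 0.0534 to 0.135); mid torpor ampulla replicates 1, 2 and 3, mid torpor zooid replicates 2 and 3, active ampulla replicate 3 and active zooid replicates 1 and 3 were among both, active ampulla replicate 1 among the former, and mid torpor zooid replicate 1 and active zooid replicate 2 among the latter. With the replicate block both calls were lost (adjusted p = 0.0707 and 0.0764), and with limma on log2(FPKM + 1) that of the latter (0.0639). The interaction of Boleac.CG.SB_v3.S555.g11570 was -11.12 and -9.21 without mid torpor zooid replicates 1 and 2 and -9.13 without active zooid replicate 3. With total counts as library size 43.1% of the interaction calls were higher, against 29.7% with TMM. The count was 3, 3 and 15 without mid torpor ampulla replicates 1, 2 and 3, 21, 4 and 20 without mid torpor zooid replicates 1, 2 and 3, 4 without active ampulla replicate 3, 23 and 12 without active zooid replicates 1 and 3, 15 with the replicate block, 121 with a block within states, 156 with the DESeq2 test, and 3 with mid torpor ampulla libraries 1 and 2 summed into 1.

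**Figure D4:**
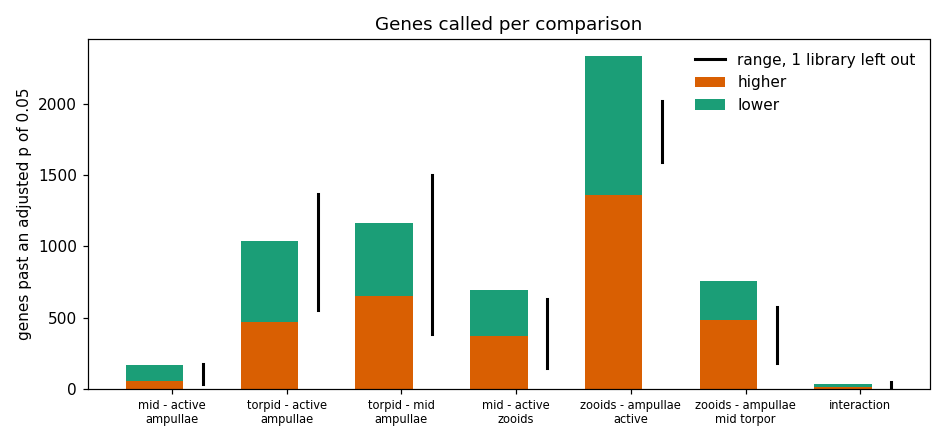
Gene models past an edgeR adjusted p of 0.05 in each of the 7 comparisons; bars stack models higher and lower in the first named group, and black lines give the range with 1 library left out. The comparison of tissues in active colonies called 2336 models and the interaction 37.

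Fold changes of different comparisons were related across gene models. Torpid minus active and mid torpor minus active ampullae shared 24 models called higher and 64 called lower, where independent lists would share 2.51 and 6.13. Their correlation was 0.315 and their covariance 0.431. Because both use the active ampullae, unchanged groups simulated against the same libraries gave a correlation of 0.503 ± 0.0211 (SD over 20 simulations), a covariance of 0.147 and no shared call. The difference of covariances was 0.284, and part of the excess of shared calls may come from the shared controls. Unchanged groups give few calls at all, so the lack of shared calls in the simulations does not measure that part. Mid torpor minus active in zooids and in ampullae, which share no library, correlated at 0.353, with 20 models called higher and 24 called lower in both against 1.99 and 3.46 for independent lists. Active ampullae and active zooids of the same number deviated together, so part of this correlation and of the excess of shared calls may come from related controls. Torpid minus active ampullae and mid torpor minus active zooids correlated at -0.0535 with all libraries and at 0.131 without torpid replicate 3, so the sign rested on that library. They shared 62 models called higher and 30 called lower, against 17.1 and 17.7 for independent lists, while 36 were higher in the former and lower in the latter and 29 the reverse, against 14.7 and 20.6.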

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

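The tests of low depth and of carried-over reads in the shallow library, and the sorting of splits by the tissue they mixed, were chosen after the result was seen. A difference between the tissues in their mid torpor response, tested as an interaction, singled out 37 gene models. Among these, Boleac.CG.SB_v3.S33.g07857 had an interaction log2 fold change of 7.45: it was higher in mid torpor than in active zooids (log2 fold change 4.92, edgeR adjusted p = 0.00724; 3.40 and 0.0444 without mid torpor zooid replicate 1), with 152.5, 32.8 and 0 CPM in mid torpor libraries 1, 2 and 3 against 2.58 ± 0.393, and stood at 1.45 ± 1.45 against 10.2 ± 8.73 CPM in ampullae. Boleac.CG.SB_v3.S30.g07155 had an interaction of 3.71, with a decrease in ampullae (log2 fold change -2.43, edgeR adjusted p = 0.0169; 0.121, 0.081 and 0.0584 without mid torpor replicates 1 and 2 and active replicate 3) and 1.28 in zooids (edgeR adjusted p = 0.138). Boleac.CG.SB_v3.S555.g11570 had -9.93, a decrease in zooids (-3.09, edgeR adjusted p = 0.042) set against an increase from 0 to 27 counts in ampullae (edgeR adjusted p = 0.0494). The call in ampullae was lost without any 1 of the 6 libraries (0.0787 to 0.156), and that in zooids without mid torpor replicates 1, 2 and 3 (adjusted p = 0.0641, 0.188 and 0.0658) or active replicates 1 and 3 (0.0793 and 0.127), with log2 fold changes of -4.28, -2.44 and -2.36 without mid torpor replicates 1 and 2 and active replicate 3. Boleac.CG.SB_v3.S39.g08859 had -9.20, lower in mid torpor zooids (-4.84, edgeR adjusted p = 0.00436) with 0 and 5 counts in active and mid torpor ampullae. All 4 calls depended on single libraries. In edgeR, Boleac.CG.SB_v3.S33.g07857 lost its call without mid torpor ampulla replicates 1, 2 and 3, mid torpor zooid replicate 1, active ampulla replicate 3 or active zooid replicate 3 (adjusted p = 0.0528 to 0.0828). Boleac.CG.SB_v3.S30.g07155 lost it without any of the mid torpor libraries, active ampulla replicate 3 or any active zooid library (adjusted p = 0.0534 to 0.135). Boleac.CG.SB_v3.S555.g11570 lost it without any mid torpor ampulla library, mid torpor zooid replicates 2 and 3, active ampulla replicates 1 and 3 or active zooid replicates 1 and 3 (adjusted p = 0.0503 to 0.0988), and Boleac.CG.SB_v3.S39.g08859 without any library of the 4 groups except mid torpor ampulla replicate 3 and active zooid replicate 2 (adjusted p = 0.0522 to 0.253). The replicate block ended the calls of Boleac.CG.SB_v3.S30.g07155, Boleac.CG.SB_v3.S555.g11570 and Boleac.CG.SB_v3.S39.g08859 (edgeR adjusted p = 0.0764, 0.0707 and 0.0995), the S-number set as a block that of Boleac.CG.SB_v3.S39.g08859 (0.0513), and limma on log2(FPKM + 1) those of Boleac.CG.SB_v3.S33.g07857 (0.437) and Boleac.CG.SB_v3.S30.g07155 (0.0639). The interaction of Boleac.CG.SB_v3.S33.g07857 was 8.35 without mid torpor ampulla replicate 1, 5.94 without mid torpor zooid replicate 1 and 6.40 without active ampulla replicate 3. That of Boleac.CG.SB_v3.S555.g11570 was -11.12 and -9.21 without mid torpor zooid replicates 1 and 2 and -9.13 without active zooid replicate 3, and that of Boleac.CG.SB_v3.S39.g08859 -9.81 without mid torpor ampulla replicate 3. The fitted values of the last 2 models depend on the prior count because active ampullae had no count.

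When the 12 libraries were regrouped within each tissue, 3 of 100 splits, the real one included, called as many models for the interaction as the real split, which called 59 in this fit of 12 libraries. That share is under 0.05, but it excludes chance only if libraries can be exchanged freely. Active libraries of the same number deviated together and mid torpor ampulla libraries 1 and 2 were nearly alike, so chance is left open here. The count, 37 in the fit of 15 libraries, was 15 with the replicate block, 121 with a block within states, 156 with the DESeq2 test and 3 with those 2 libraries summed into 1. The highest other split called 231, several times the real number. Both other splits that reached 59 were among the 8 that kept the zooid libraries in their states and mixed the ampullae, so the difference between zooid states stayed in them and they do not stand for chance alone; the 83 splits that mixed both tissues called at most 4. For each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, reached the real number, and 10 splits are too few for a share under 0.05. In fits of the 6 libraries, the real and highest other counts were 160 and 0 for mid torpor minus active ampullae, 242 and 4 for torpid minus active ampullae, 931 and 0 for torpid minus mid torpor ampullae, 960 and 0 for mid torpor minus active zooids, 2058 and 0 for active zooids minus ampullae (also where a split parted all 3 same-numbered libraries), and 1147 and 0 for mid torpor zooids minus ampullae.

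The shallow mid torpor zooid library stood apart on the second principal component of all 15 libraries, at 78.3, where the others lay between -34.1 and 9.93. Low depth alone can place a library this far out. The other mid torpor zooid libraries were thinned to 17121 counts, each in a component analysis of its own without the shallow library. The copies stood at up to 82.6 in size on the second component, with means of 81.7 and 71.3. Projected instead onto the component of all 15 libraries, which the shallow library helped to set, the copies stood at only 31.5 and 30.1. Whether low depth accounts for its whole position is therefore left open. Reads carried over from the other 14 libraries would make its profile resemble their mean, but it correlated better with the 2 deeper mid torpor zooid libraries, by 0.0645, where a thinned pool of the 14 gave -0.135 ± 0.00568 (SD over 20 draws). A library built from few starting molecules stays open: 4479 gene models had a count, within the 4458 to 4690 of thinned copies of the other mid torpor zooid libraries but below their mean of 4571. No biological explanation was tested for a single library.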

How the results depend on the processing

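All alternatives called added were chosen after the data were seen. The balance of higher and lower calls changed direction in several comparisons. For mid torpor minus active zooids it went from 373 and 321 to 315 and 438 with DESeq2 size factors, 391 and 533 with the DESeq2 test, 360 and 544 on log2(FPKM + 1) (348 and 555 without a filter), 425 and 535 in the fit of only these groups, 674 and 1227 with a block there (added), and 258 and 317 without active zooid replicate 2. For torpid minus mid torpor ampullae it went from 655 and 505 to 412 and 519 in the fit of only these groups and 68 and 159 on log2(FPKM + 1), 62 and 150 there without a filter, 307 and 353 with a block of 2 groups and 262 and 305 with mid torpor libraries 1 and 2 summed (both added), and it also turned on log2(FPKM + 0.1) and without any 1 mid torpor ampulla library. For torpid minus active ampullae it went from 471 and 569 to 504 and 314 with the mean of both active tissues as reference and to 382 and 343 without torpid replicate 3, or 385 and 376 without the shallow library as well (added), where the interaction went from 11 and 26 to 34 and 33. Mid torpor minus active ampullae went from 55 and 111 to 43 and 40 without mid torpor replicate 3. The 28 log2 fold changes of named gene models kept their sign in all 359 alternatives and lost the call in 72, mostly where a library was left out. The 4 medians of tissue-biased models (all added) kept their sign in all 84 alternatives, and camera's call at the preset correlation held wherever it was run. With an estimated correlation the camera adjusted p of the zooid-higher sets reached 0.0831 in torpid minus mid torpor and 0.0767 in torpid minus active ampullae. The call was lost in most alternatives of the former and in several of the latter. The medians ran from 1.23 to 2.10 and -1.10 to -0.66 for zooid-higher and ampulla-higher models in torpid minus mid torpor, and from 1.04 to 2.01 and -1.83 to -1.07 in torpid minus active ampullae. Counts of calls depended on single libraries. With 1 library left out they ran from 34 to 178 for mid torpor minus active ampullae, 552 to 1368 for torpid minus active, 388 to 1496 for torpid minus mid torpor, 147 to 628 for mid torpor minus active zooids, 1588 to 2016 for zooids minus ampullae in active and 185 to 578 in mid torpor colonies, and 3 to 52 for the interaction. The remaining counts are those that differed from the reported one by more than 1.5 times; unless stated, the cause was not tested.

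Tests on FPKM called fewer models in all comparisons but mid torpor minus active zooids, where log2(FPKM + 1) gave 904 with and 903 without a filter and log2(FPKM + 0.1) gave 342. On log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, the counts were 47, 21 and 48 for mid torpor minus active ampullae, 333, 205 and 314 for torpid minus active, 227, 184 and 212 for torpid minus mid torpor, 1214, 608 and 1242 for active zooids minus ampullae, 403, 266 and 386 for mid torpor zooids minus ampullae, and 15, 0 and 14 for the interaction. Where limma on log2(FPKM + 0.1) called 0 models for the interaction, edgeR gave 1059 models at an unadjusted p under 0.05 and DESeq2 called 156. DESeq2 called 311 for mid torpor minus active ampullae. Fits of only the groups compared called 242 for torpid minus active, 1147 for mid torpor zooids minus ampullae and 59 for the interaction. The fit of 15 libraries gave 1040, 759 and 37, so these moves went both ways. Without both the shallow library and torpid replicate 3 (added), the counts were 611 for torpid minus mid torpor and 67 for the interaction. With mid torpor ampulla libraries 1 and 2 summed into 1 (added), they were 44 for mid torpor minus active ampullae, 567 for torpid minus mid torpor, 272 for mid torpor zooids minus ampullae and 3 for the interaction.

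The replicate block over all 15 libraries moved only the interaction, to 15. It left 2279 calls for active zooids minus ampullae, the one comparison in which the numbers paired the libraries. In no other comparison did all 6 libraries correlate best with their own number. By the set of the S number all 6 did so in active ampullae against active zooids (0.196, 0.212 and 0.215), where both labels pair the same libraries. Mid torpor against torpid ampullae (0.0912, 0.0759 and 0.189) and active ampullae against mid torpor zooids (0.0782, 0.105 and 0.122) did so too. Some of their values were under 0.1. Ampulla and zooid descriptions share a code for active replicates 1 and 2 and for mid torpor replicates 2 and 3. The meaning of these codes is not given in the sources used here. The correlations were 0.215 and 0.196 for these active pairs and 0.0133 and 0.0769 for these mid torpor pairs. A block in fits of 2 groups (added) gave 11 for mid torpor minus active ampullae, 157 for torpid minus active, 660 for torpid minus mid torpor, 1901 for mid torpor minus active zooids and 1193 for mid torpor zooids minus ampullae; within states, the interaction called 121. With the S-number set as a block no count moved by more than 1.5 times. Tests of gene lists by symbol were not run. At the depth of the shallow library, 3 counts corresponded to 175 CPM before TMM scaling, and 1 count to 35 CPM after it. Changes below the level of 3 counts were not detectable there.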

Other observations

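All tests given here were chosen after the result was seen. Gene models that changed the same way in both tissues at mid torpor form a small shared set. Of the 24 that were lower in both zooids and ampullae (median log2 fold changes -1.91 and -2.10), 23 had a negative fold change in torpid minus active ampullae and 13 were called lower there, with a median of -1.58. Of the 20 that were higher in both (medians 2.35 and 2.47), 12 had a positive fold change in torpid ampullae, 6 were called higher and 3 lower, and the median was 0.37. Active ampullae enter both the choice and the torpid comparison, which favours the same sign. Boleac.CG.SB_v3.S5.g10797 stood at 32.2 ± 16.6 CPM (SD, n = 3) in mid torpor ampullae and at 28.25, 13.45 and 0 in mid torpor zooid libraries 1, 2 and 3, against 0.44 ± 0.762 and 0.102 ± 0.176 in the active tissues and 5.63 ± 3.22 in torpid ampullae.

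Along the sequence from active through mid torpor to torpid ampullae, 26 of the 55 models called higher in mid torpor were called lower again in torpid ampullae and 2 rose further; of the 111 called lower, 30 were called higher again and 7 fell further. Mid torpor ampullae enter both steps with opposite signs, so chance alone favours reversal here. Neighbouring gene models tended to change together. Among 7430 adjacent models by identifier without identical values, 108 were called in the same direction in torpid minus active ampullae, where 1000 permutations gave a mean of 38.2 and a maximum of 57 (permutation p = 0.001, the smallest they can give). For active zooids minus ampullae the number was 407, against a permuted mean of 196 (permutation p = 0.001). Fold changes showed little relation to the gene length implied by counts and FPKM: Spearman's rho across models was -0.05 for torpid minus active ampullae, and the zooid-higher median there was 1.51 after a length trend was removed, over 485 of 486 models with a length.

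Torpid libraries lay towards the zooid side of the tissue-biased models. Torpid replicate 3 alone does not account for this: without that library the median log2 fold change of zooid-higher models in torpid minus active ampullae was 1.04, camera's call at the preset correlation held, and with an estimated correlation the adjusted p = 0.0581 (0.00647 to 0.0767 over the alternatives). Active zooid RNA mixed into active ampulla RNA would need 1 share for both kinds of models, but zooid-higher models required 10.7% and 35.2% in torpid replicates 1 and 2 and ampulla-higher models 73.4% and 92.4%, gaps of 62.7 and 57.2 percentage points. Known mixtures, all with a true share of 30%, were estimated at 21.8% to 47.8% and had gaps of up to 10.8. In replicate 3 the gap was 18.1 points (78.4% and 96.6%), so active zooid RNA there cannot be told apart from a change in the ampullae, since 1 library decides and known mixtures come near that gap. For RNA with the mid torpor zooid profile the base was mid torpor ampulla RNA, with 996 zooid-higher and 474 ampulla-higher models of active colonies. The shares of active zooid RNA in the torpid libraries used 397 and 223 models of mid torpor colonies. The mid torpor profile required 28.9% and 51.9% by zooid-higher models in torpid replicates 1 and 2, and 73.8% and 97.7% by ampulla-higher models. In replicate 3 the order was reversed, with 170% and 107%, both above what a mixture can hold. The shares of the mid torpor profile were at least 44.9 points apart in each torpid library, which argues against that mixture as the whole cause. No known mixture of mid torpor libraries was made, so the error of these shares is not known. A change within the ampullae, zooid RNA of a torpid profile not sampled here and a sample that held other parts of the colony were not tested and stay open.

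Torpid ampullae and mid torpor zooids differed at 7 gene models in edgeR (2 higher and 5 lower in torpid), 11 without the shallow library and 6 (5 higher and 1 lower) without torpid replicate 3, and 1267 models had an unadjusted p under 0.05, where 515 are expected by chance. DESeq2 called 160 models. The SD of log2 fold changes of abundant models was 0.73 against 0.50 ± 0.0077 (SD over 10 simulations) with no difference. Real models vary together, and shared shifts of single libraries can also widen this SD and raise the number of low unadjusted p-values. These values therefore cannot decide whether differences were left below the threshold. In simulated counts for this comparison edgeR recovered 47% of models changed by a log2 fold change of 2 and 72% of those changed by 3, so too little power for smaller changes stays open as a reason for the low number. Whether the resemblance reflects a shared state of the colony or the tissue sampled was not tested.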
